A study of Mus musculus with 15 samples.

How the data were processed

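RNA was sequenced in bulk from adipocyte precursor cells that had been sorted by flow cytometry from the subcutaneous adipose tissue of C57Bl/6 mouse pups, per the labels' protocols. The sort took CD24+ cells, which the submitters call progenitors, and CD24− cells, which they call preadipocytes. Wildtype pups had been fostered to dams whose milk held either a high or a low ratio of n6 to n3 polyunsaturated fatty acids. One protocol gives the exposure as 12 days and another as 10 days, and both are reported here as stated. Libraries were made with a NuGEN Universal Plus mRNA kit, per the labels' protocols. The submitters' processing notes name Salmon 0.14.2, DESeq2 1.28.1 and the builds mm10 and GRCm38. The annotation release and the strand setting are not given in the sources used here.

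The data came as 2 tables, 1 per sorted population, and each had been normalized by the authors on its own. The sample columns hold deposited expression values on the log2-like scale of the variance stabilizing transformation, with a floor shared by all samples of a table (7.70 in progenitors and 7.12 in preadipocytes). Each table also holds the authors' log2 fold change, p-value and adjusted p-value for the comparison of milks, which were used here only as a second source beside the tests described next. No sample column was left unmapped. Of the gene IDs, 23322 of 23347 in the progenitor table and 23096 of 23118 in the preadipocyte table matched a symbol, a GC content and a length in GENCODE M21 on GRCm38, which was used for names, coordinates, GC content and transcript length, the last pair as medians over the transcripts of a gene.

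Samples were grouped by the fatty acid ratio given in their characteristics: 4 progenitor samples on high-ratio milk, 4 progenitor samples on low-ratio milk, 3 preadipocyte samples on high-ratio milk and 4 preadipocyte samples on low-ratio milk. For 4 samples, the preadipocytes on low-ratio milk, the source name gives the high ratio instead. The characteristics were used. Those samples carry the numbers 108, 114, 119 and 133, which in progenitors belong to the low-ratio samples in both fields. The labels do not say how many animals went into a sample, so p-values measure the spread between these samples, part of which may be technical.

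The variance stabilizing transformation was inverted in closed form to give normalized counts. Recomputed group means were checked against the authors' log2 fold changes: at a mean of at least 100 the median absolute difference was 0.000751 over 11162 genes in progenitors and 0.00304 over 11076 genes in preadipocytes. Low values tended to fall on whole multiples of 1 step per library, the worth of 1 read, and the step gave an estimate of the reads per library. With a tolerance of 0.02, the share of values up to 20 reads that came out whole ranged from 39.9% to 82.5% over genes with 1 transcript and from 25.8% to 57.8% over all genes. Because whole reads were recovered for only part of the genes, no count-based test was run, and the tests listed for counts before the data were examined were replaced by those for normalized values. Estimated depth ranged from 13.8 to 68.7 M reads (M, mega) and is given per library with the results.

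Differences between milks were tested within each table with limma 3.58.1 in R 4.3.3, on log2(normalized count + 1), with the intensity trend and robust options and Benjamini-Hochberg adjustment at 0.05, for genes with a mean of at least 10. Every fold change is low minus high on that scale, which understates the change of genes with few reads. Each fold change is given with its standard error from limma, and each mean normalized count with the SD over the libraries of the group. The difference in milk effect between populations was tested as an interaction in a fit of all 15 samples with a mean per group, over the genes tested in both populations. Each table carries its own normalization, so levels of the populations were not compared by a test. Such a shift between tables is the same for both milks and drops out of the interaction.

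The 27 gene lists and 12 lists of cell type markers were fixed before the data were examined, as were the groups, the tests, the first set of alternatives and the rule for the genes named. Lists with at least 3 measured members were tested with camera at a preset correlation of 0.01 and, as alternatives, with camera at an estimated correlation and with fry, in each case with Benjamini-Hochberg adjustment over the lists of the same kind. The rule named, in each direction, the 10 genes with the largest fold change among those past the threshold whose groups did not overlap, leaving out provisional names. Where fewer than 5 passed, it added the genes with the smallest p, up to 5. From each gene list it took up to 4 members with the smallest p, from each marker list up to 3 members with the highest level, and always Cd24a, Nr2f2, Cpt1a, Ppargc1a, Pparg and Pdgfra. Members of lists named in the interaction follow from those of the separate comparisons. Genes outside the rule are said to have been chosen after their values were seen.

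The alternatives were median-ratio rescaling, quantile normalization, no filter, a minimum mean of 100, sample quality weights, pseudocounts of 0.1 and 5, a threshold of 0.1, the balance of Y-linked genes to Xist as a covariate, each library left out in turn and a replicate block. A count-based fit with other size factors, a Wald test on counts, a fit with a common normalization of both tables and a comparison of progenitors with preadipocytes were not run, for lack of whole reads and a shared scale. Added after seeing the data were the variance-stabilized values as deposited, a smooth trend on GC content and transcript length (4 spline degrees of freedom each) removed from every library, and the list tests of the interaction. The tests were run on simulated data with 200 changed genes per draw and 3 draws per comparison. Of genes changed 2-fold, the test recovered 41.8% in progenitors (15959 genes in the first draw), 30.2% in preadipocytes (15861 genes) and 27.0% in the interaction (15176 genes). At 4-fold the shares were 76.8%, 70.6% and 66.3%. Over the 3 draws, 12, 11 and 15 unchanged genes were called, in the same order, and 0 of 81 lists of unchanged genes were called in either population. The simulated genes were drawn independently of each other. The simulated lists thus say nothing on false calls from lists whose genes are correlated. Figures and tables of normalized counts were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.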

Results

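The series compares mouse pups raised on milk with a low or a high ratio of n6 to n3 polyunsaturated fatty acids. Its title puts lipid oxidation in adipocyte precursor cells as the question. Bulk RNA-seq values were analysed for 15 libraries. CD24+ progenitors, the earlier precursors, gave 4 libraries on high-ratio and 4 on low-ratio milk. CD24− preadipocytes, the later precursors, gave 3 libraries on high-ratio and 4 on low-ratio milk. Libraries carry the numbers 1015, 1017, 1018 and 1019 on high-ratio milk and 108, 114, 119 and 133 on low-ratio milk, with no preadipocyte library for 1018. Within a group, pairs of libraries correlated at Pearson coefficients from 0.926 to 0.960 across genes. Over the genes with a mean of at least 10, at most 0.401% of values in a pair of libraries of a group were exactly equal, with no tolerance and genes at 0 in both counted as equal.

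Estimated depth was 38.6 M (108), 34.4 M (114), 39.3 M (119) and 39.2 M reads (133) in progenitors on low-ratio milk and 42.6 M (1015), 40.9 M (1017), 40.4 M (1018) and 59.3 M reads (1019) in progenitors on high-ratio milk. In preadipocytes it was 36.5 M (108), 42.8 M (114), 35.3 M (119) and 49.8 M reads (133) on low-ratio milk and 13.8 M (1015), 68.7 M (1017) and 22.8 M reads (1019) on high-ratio milk. The CD24 gene used for the sort, Cd24a, had 2281 ± 442 (SD, n = 4) and 2209 ± 210 normalized counts (SD, n = 4) in progenitors on high-ratio and low-ratio milk, against 631 ± 76.5 (SD, n = 3) and 616 ± 52.1 (SD, n = 4) in preadipocytes. The tables of the populations were normalized separately, so these levels were not compared by a test. Cd24a passed the threshold between milks in neither population (log2 fold change −0.03 ± 0.14 SE in both, limma adjusted p = 0.968 and 0.912).

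In preadipocytes, low-ratio milk went with lower expression of mitochondrially encoded genes, of part of the ribosomal protein and nuclear respiratory chain genes, and of the inflammatory genes Ccl7, Il6 and Ccl2. These inflammatory genes were exceptions in a list of NF-kB inflammatory genes that was not called and most of whose members had higher values. Low-ratio milk went with higher expression of Gpd2, the mitochondrial glycerol-3-phosphate dehydrogenase, of the amino acid transporter gene Slc7a5 and of the fatty acid desaturase gene Fads2. Gpd2 had 114 ± 22.7 normalized counts (SD, n = 3) on high-ratio and 958 ± 331 (SD, n = 4) on low-ratio milk, a log2 fold change of 3.0 ± 0.31 (SE, adjusted p = 0.0152). The mitochondrial cytochrome b gene mt-Cytb had 381128 ± 61957 (SD, n = 3) and 163006 ± 16213 normalized counts (SD, n = 4), a log2 fold change of −1.22 ± 0.13 (SE, adjusted p = 0.0186). Of 15893 genes tested with limma, 458 passed an adjusted p of 0.05, 85 of them higher and 373 lower on low-ratio milk. At an unadjusted p under 0.05 there were 3454 genes, 1680 higher and 1774 lower. In 21.1% of genes tested the groups did not overlap, where chance gives 5.71%. With the trend on GC content and transcript length removed, 9 genes passed (7 higher and 2 lower). The lower ones are processed pseudogenes. Of the 7 genes named in this paragraph only Gpd2 passed (adjusted p = 0.0211), while mt-Cytb (0.0503), Slc7a5 (0.0526), Ccl7 (0.0649), Fads2 (0.0738), Ccl2 (0.0815) and Il6 (0.102) did not. The removal took the log2 fold changes of Gpd2 from 3.0 to 2.87, Slc7a5 from 2.45 to 2.41 and Fads2 from 0.58 to 0.51. It took those of mt-Cytb from −1.22 to −0.76, Ccl7 from −1.13 to −0.83, Ccl2 from −0.80 to −0.58 and Il6 from −0.99 to −0.49. Without 1 library, 2 (high 1015), 0 (high 1017), 7 (high 1019), 0 (low 108), 4 (low 114), 1 (low 119) and 1 (low 133) of these 7 genes passed.

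The largest rises named by the fixed rule were those of Myo5b, a myosin motor of recycling endosomes (log2 fold change 3.90 ± 0.39 SE, adjusted p = 0.0152), Fbxw7, a substrate receptor of a ubiquitin ligase (3.17 ± 0.38 SE, adjusted p = 0.0204), and Gpd2. They were followed by Polr3g (2.53), Slc7a5 (2.45), the replication fork gene Donson (2.32), Trim46 (2.24), Cdnf (2.21), the hypoxia-inducible factor gene Hif3a (2.11) and Vav2 (1.97). Slc7a5 had 232 ± 33.0 normalized counts (SD, n = 3) on high-ratio and 1363 ± 514 (SD, n = 4) on low-ratio milk. In each of these 10 genes every low-ratio library lay above every high-ratio library. Among the 10 largest falls, Rpl17-ps5 was listed at 0 in all 4 low-ratio libraries and at 114, 27.9 and 52.7 normalized counts in the high-ratio libraries 1015, 1017 and 1019. The others were Ptpn6, a phosphatase of blood cells (−3.79 ± 0.80 SE, adjusted p = 0.0468), Rpsa-ps2 (−2.93), Xlr (−2.0), Zfp808 (−1.69), AW112010 (−1.67), P2ry10b (−1.64), Aspa (−1.64), the proteoglycan gene Ogn (−1.55 ± 0.25 SE, adjusted p = 0.0332) and Zfp967 (−1.54). Rpl17-ps5 and Rpsa-ps2 are pseudogenes and Xlr belongs to a multicopy family, so their values are uncertain because reads can be shared with near-identical copies.

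On GRCm38, Gpd2 (ENSMUSG00000026827) lies on chromosome 2 from 57237635 to 57370719 on the plus strand. Myo5b (ENSMUSG00000025885) lies on chromosome 18 from 74440936 to 74771493 on the plus strand, and Donson (ENSMUSG00000022960) on chromosome 16 from 91676808 to 91688770 on the minus strand. Fads2 (ENSMUSG00000024665) lies on chromosome 19 from 10062765 to 10101746 on the minus strand. Postn (ENSMUSG00000027750) lies on chromosome 3 from 54361109 to 54391037 on the plus strand, and Dnah2 (ENSMUSG00000005237) on chromosome 11 from 69420809 to 69549110 on the minus strand. The mitochondrial gene mt-Cytb (ENSMUSG00000064370) spans 14145 to 15288 of the mitochondrial genome on the plus strand. All are annotated as protein coding, and values are sums over whole genes, not over single exons.

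**Figure D1:**
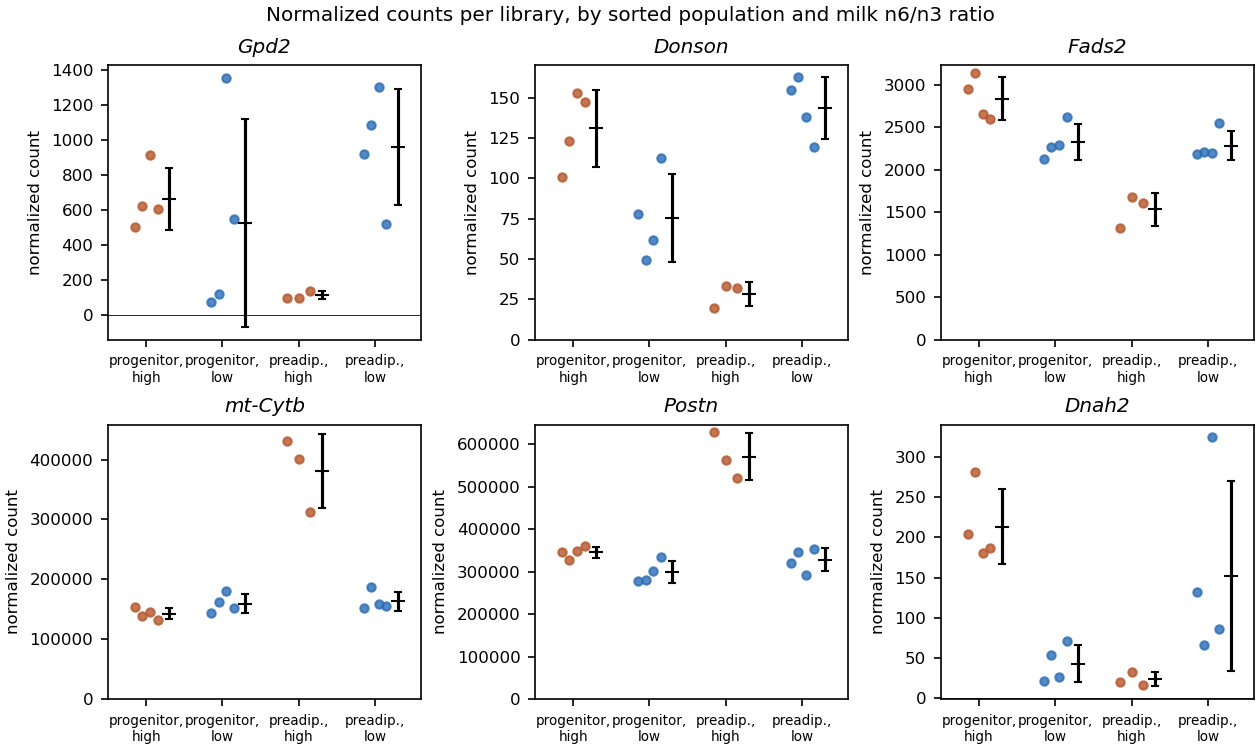
Normalized counts per library of Gpd2, Donson, Fads2, mt-Cytb, Postn and Dnah2 (y axis) by sorted population and milk ratio (x axis). Each point is 1 library, orange for high-ratio and blue for low-ratio milk, and the black bar beside it is the mean with the SD. In preadipocytes Gpd2 rose from a mean of 114 to 958, and mt-Cytb fell from a mean of 381128 to 163006.

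All 13 measured mitochondrially encoded genes had lower values in preadipocytes on low-ratio milk, and 10 of them fell (12 when adjusted over the list alone), with a median log2 fold change of −1.01. Camera gave the list an adjusted p of 2.3e-14. With an estimated correlation the call was lost (adjusted p = 0.42 with an estimated correlation), while fry, which asks whether the genes move one way on balance, gave an adjusted p of 0.0089. Examples are mt-Atp8 (−1.44), mt-Nd6 (−1.34) and mt-Nd4l (−1.05). With the trend on GC content and transcript length removed, the list's median was −0.32 (camera adjusted p = 0.00017). The genes mt-Atp8 and mt-Nd4l overlap their neighbours and mt-Nd6 lies on the other strand, so reads of these genes cannot be fully told apart from those of their neighbours. All genes with a symbol that starts with mt-, tRNA genes included, are a wider set than the list. They took 6.35% (1015), 5.83% (1017) and 4.54% (1019) of normalized counts on high-ratio milk. On low-ratio milk they took 2.61% (108), 3.03% (114), 2.73% (119) and 2.50% (133). Of 50 nuclear-encoded respiratory chain genes, 11 fell and 0 rose (14 fell when adjusted over the list alone), with a median of −0.14 and a camera adjusted p of 0.00033 (adjusted p = 0.78 with an estimated correlation). They included Uqcrb (−1.27 ± 0.19 SE, adjusted p = 0.0256), Ndufb3 (−1.10), Ndufv2 (−0.96) and Ndufa1 (−0.69). Of 48 cytosolic ribosomal protein genes, 16 fell and 0 rose (26 fell when adjusted over the list alone), with a median of −0.50 and a camera adjusted p of 7.4e-10 (adjusted p = 0.78 with an estimated correlation). Rpl24 (−1.32), Rps24 (−1.10), Rps12 (−0.96) and Rpl35 (−0.76) were among them.

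**Figure D2:**
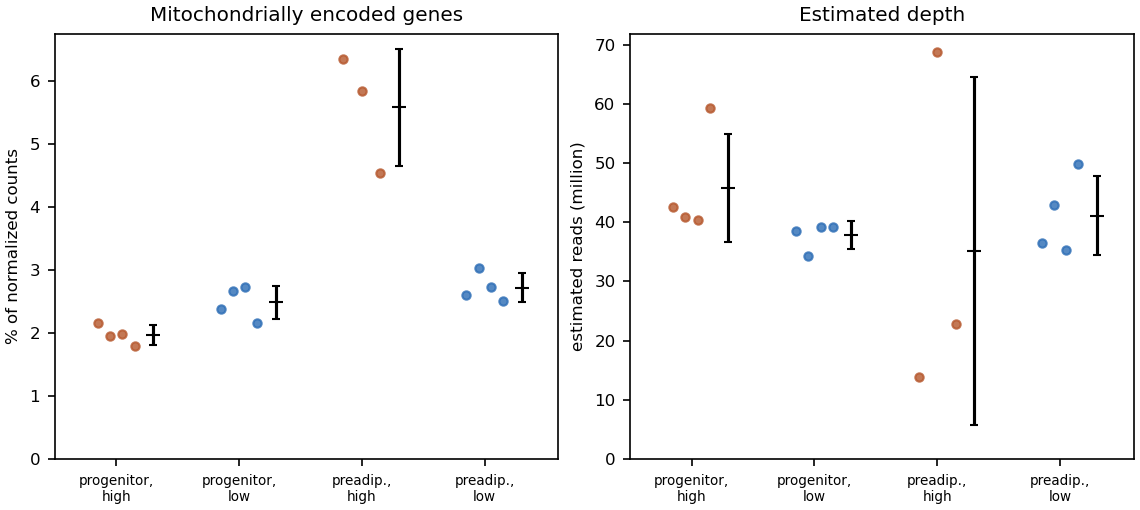
Left, share of normalized counts in percent from mitochondrially encoded genes, here all symbols that start with mt-. Right, estimated depth in M reads. Both are shown per library, by population and milk ratio. Points are libraries and black bars are means with the SD. The preadipocyte libraries on high-ratio milk lie between 4.54% and 6.35%, above the 2.50% to 3.03% of those on low-ratio milk, and include both the shallowest (13.8 M) and the deepest (68.7 M reads) library.

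Genes of fatty acid synthesis and desaturation had higher values on low-ratio milk in 14 of 15 measured members. Fads2, the delta-6 desaturase of polyunsaturated fatty acid synthesis, rose from 1533 ± 193 (SD, n = 3) to 2282 ± 174 normalized counts (SD, n = 4), a log2 fold change of 0.58 ± 0.12 (SE, adjusted p = 0.0441). It was the list's 1 member past the threshold over all genes, while 6 passed when adjusted over the list alone. Fads1 (0.58, adjusted p = 0.0526), Scd2 (0.52, adjusted p = 0.101) and Scd1 (0.39, adjusted p = 0.0951) stayed short of it. The list's median was 0.33, with a camera adjusted p of 0.00093 (adjusted p = 0.78 with an estimated correlation). Glycolysis (median 0.30 over 17 genes, camera adjusted p = 0.011) and cholesterol synthesis (median 0.30 over 25 genes, camera adjusted p = 0.017) were also called higher, each with 0 members past the threshold, in both counts, and an adjusted p = 0.78 with an estimated correlation. Pfkp (0.35, adjusted p = 0.0878) is an example from glycolysis. The call of glycolysis ended without high 1015 (adjusted p = 0.156), and that of cholesterol synthesis without high 1015 (0.0813), high 1017 (0.119), low 119 (0.0774) or low 133 (0.0501). Removing the trend on GC content and transcript length also ended the call of glycolysis (camera adjusted p = 0.0665).

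Genes of fatty acid oxidation, the process that the title names, were not called as a list in preadipocytes. Of 22 mitochondrial fatty acid oxidation genes 0 passed, over all genes and when adjusted over the list alone, with a median of 0.13 and a camera adjusted p of 0.6. Cpt1a, the carnitine palmitoyltransferase that admits fatty acids to mitochondria, had a log2 fold change of 0.39 ± 0.21 (SE, adjusted p = 0.309), Acadl 0.34 (adjusted p = 0.162) and Decr1 −0.52 (adjusted p = 0.098). Peroxisomal oxidation (median 0.07 over 14 genes, 0 past the threshold in either count, camera adjusted p = 0.9) was not called either. Among 17 targets of the nuclear receptor PPAR, 1 fell, in both counts, the fatty acid transporter gene Cd36 (−0.83 ± 0.12 SE, adjusted p = 0.023), and the list was not called (median 0.06, camera adjusted p = 0.6). Sucla2 (−0.97, adjusted p = 0.0365) fell among 18 citric acid cycle genes (2 higher and 1 lower when adjusted over the list alone), a list with a median of 0.09 and a camera adjusted p of 0.52. Ppargc1a had −0.75 ± 0.62 (SE, adjusted p = 0.511), Pparg 0.30 ± 0.27 (SE, adjusted p = 0.539), Nr2f2 0.02 ± 0.24 (SE, adjusted p = 0.973) and Pdgfra 0.35 ± 0.21 (SE, adjusted p = 0.367).

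**Figure D3:**
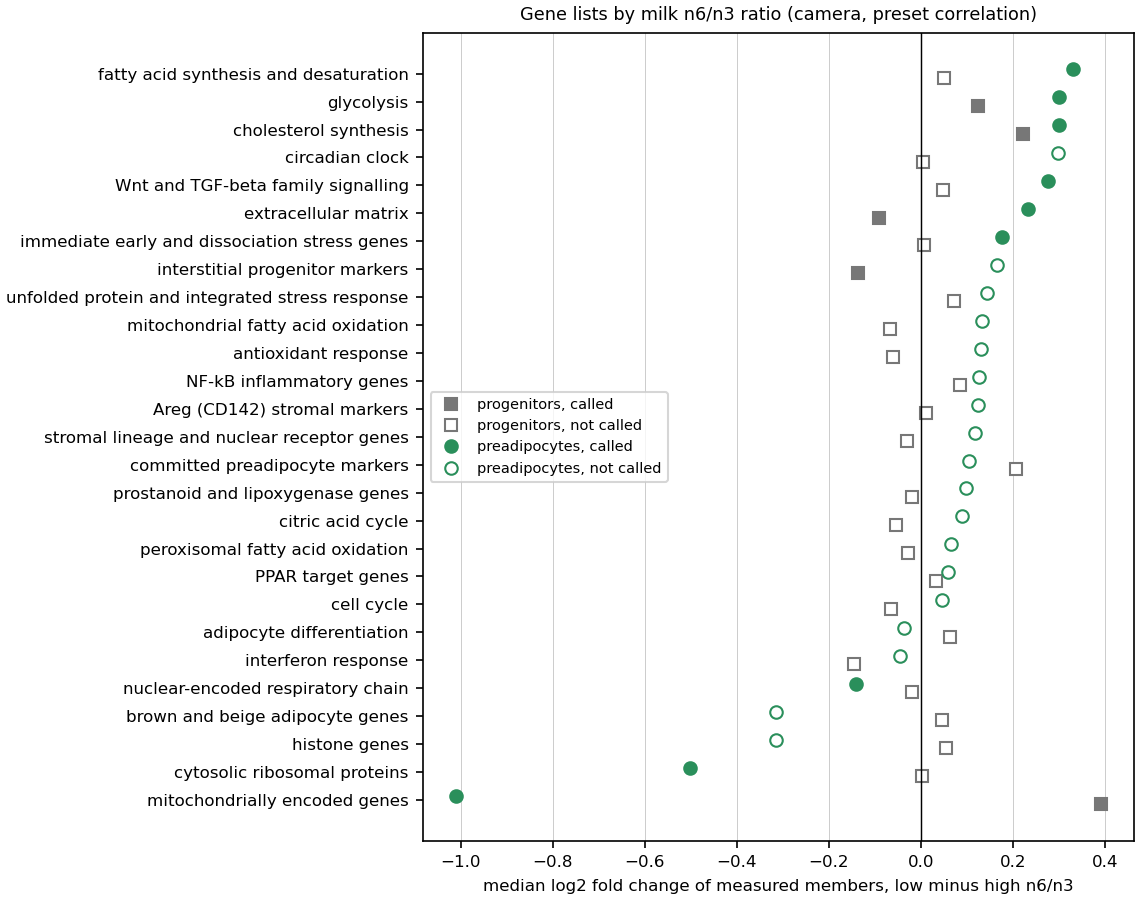
Median log2 fold change, low minus high milk ratio (x axis), of the measured members of each gene list (y axis) in progenitors (grey squares) and preadipocytes (green circles). Filled symbols mark lists called by camera at the preset correlation of 0.01 and an adjusted p of 0.05. Mitochondrially encoded genes have medians of −1.01 in preadipocytes and 0.39 in progenitors.

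Of 29 extracellular matrix genes, Postn (−0.80 ± 0.10 SE, adjusted p = 0.0204) and Lum (−0.77 ± 0.11 SE, adjusted p = 0.023) fell, while 25 of the 29 had higher values, and the list was called higher (median 0.23, camera adjusted p = 0.0075; adjusted p = 0.78 with an estimated correlation). When adjusted over the list alone, 6 genes were higher and 2 lower. Col1a1 (0.47, adjusted p = 0.0753) and Sparc (0.47, adjusted p = 0.0635) had higher values without passing. Wnt and TGF-beta family genes (median 0.28 over 25 genes, 0 past the threshold and 2 when adjusted over the list alone, camera adjusted p = 0.02; adjusted p = 0.78 with an estimated correlation) and immediate early genes (median 0.18 over 31 genes, 0 in either count, camera adjusted p = 0.036; adjusted p = 0.81 with an estimated correlation) were called higher as well. Immediate early genes respond to tissue dissociation as well as to signalling. Without high 1015 the calls of the matrix (adjusted p = 0.0813), Wnt and TGF-beta family (0.111) and immediate early genes (0.239) ended. Those of the latter lists ended without low 114 (0.0764 each), and that of immediate early genes without low 119 (0.274) or low 133 (0.0501). Removing the trend on GC content and transcript length ended the calls of the matrix (camera adjusted p = 0.347), Wnt and TGF-beta family (0.234) and immediate early genes (0.876). Fry's mixed test, which asks whether genes change in either direction, passed for 18 of the 27 lists.

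Single members changed in lists that were not called. The chemokine genes Ccl7 (−1.13 ± 0.14 SE, adjusted p = 0.0204) and Ccl2 (−0.80, adjusted p = 0.0347) and the cytokine gene Il6 (−0.99, adjusted p = 0.0331) fell among 23 NF-kB inflammatory genes, 15 of which had higher values (1 higher and 3 lower when adjusted over the list alone, camera adjusted p = 0.97). Mgst1 (−1.29) and Prdx1 (−0.96) fell among 22 antioxidant genes (1 higher and 3 lower when adjusted over the list alone, camera adjusted p = 0.45). Among 19 prostanoid and lipoxygenase genes, Hpgd, which degrades prostaglandins, fell by 0.96 on the log2 scale (adjusted p = 0.0365) and the epoxide hydrolase gene Ephx1 rose by 0.71 (adjusted p = 0.0365), with 2 higher and 1 lower when adjusted over the list alone and a camera adjusted p of 0.94. The replication licensing gene Mcm2 rose by 1.20 (adjusted p = 0.023) among 30 cell cycle genes (2 higher when adjusted over the list alone, camera adjusted p = 0.73), and the histone gene H3f3a fell by 0.71 (adjusted p = 0.0441) among 8 histone genes (3 lower when adjusted over the list alone, camera adjusted p = 0.18).

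Markers of other cell types gave 1 call in preadipocytes. Erythroid genes were lower on low-ratio milk (median −1.01 over 5 genes, 0 past the threshold in either count, camera adjusted p = 0.023; adjusted p = 0.87 with an estimated correlation), with Hbb-bs at 2042 ± 1735 (SD, n = 3) against 870 ± 300 normalized counts (SD, n = 4). The other 9 lists measured were not called, although the endothelial gene Tek (0.61, adjusted p = 0.0469) and the Schwann cell gene Pmp22 (0.40, adjusted p = 0.0497) rose. Every library of both populations held both Xist and Ddx3y RNA. In preadipocytes Xist had 4259 ± 1075 (SD, n = 3) and 1540 ± 1229 normalized counts (SD, n = 4) on high-ratio and low-ratio milk (adjusted p = 0.126), and the Y-linked gene Ddx3y 1289 ± 766 (SD, n = 3) and 1330 ± 416 (SD, n = 4).

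Fold changes in preadipocytes also went with the GC content of the transcripts. Across genes, which are not independent replicates, Spearman's rho between fold change and GC content was 0.265 in preadipocytes and 0.00722 in progenitors. Of 5 equal bins of genes ordered by GC content, the lowest (median 42.0%) had a median log2 fold change of −0.24 and the highest (58.1%) one of 0.13. Of the 373 genes that were lower on low-ratio milk, 212 lay in the lowest bin, as did 7 of the 85 that were higher. Removing a smooth trend on GC content and transcript length left 9 genes past the threshold. Among them were Myo5b, Gpd2, Fbxw7 and Donson, with log2 fold changes of 3.86, 2.87, 3.20 and 2.26. Those still lower, Gm10259 (−6.58) and Gm48499 (−6.62), and the higher Gm3851 (6.31) are processed pseudogenes. Their values are uncertain because reads can be shared with near-identical copies. The median of the mitochondrially encoded genes was then −0.32 (camera adjusted p = 0.00017), and those of fatty acid and cholesterol synthesis were 0.17 and 0.16. Ribosomal proteins (−0.46, camera adjusted p = 1.9e-10) and the nuclear respiratory chain (−0.11, camera adjusted p = 0.00044) were still called lower. In the test without the correction these calls and that of mitochondrially encoded genes were lost (adjusted p = 0.78, 0.78 and 0.42 with an estimated correlation). The calls of glycolysis (adjusted p = 0.0665), the extracellular matrix (0.347), the Wnt and TGF-beta family (0.234) and immediate early genes (0.876) ended. The authors' deposited table listed 1834 genes at an adjusted p under 0.05 in preadipocytes, 690 higher and 1144 lower, and all 458 genes called here were among them with the same direction. With the balance of Y-linked genes to Xist as a covariate, 0 genes passed in limma (1945 at an unadjusted p under 0.05). The median fold of the 458 genes, each in its own direction, was 0.98 with and without the covariate, and their median SE was 0.24 with and 0.18 without it. Leaving out 1 library gave 16 (high 1015), 7 (high 1017), 1160 (high 1019), 2 (low 108), 13 (low 114), 16 (low 119) and 4 (low 133) genes past the threshold. Of these, in the same order, 10, 7, 347, 0, 5, 4 and 2 were higher on low-ratio milk.

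**Figure D4:**
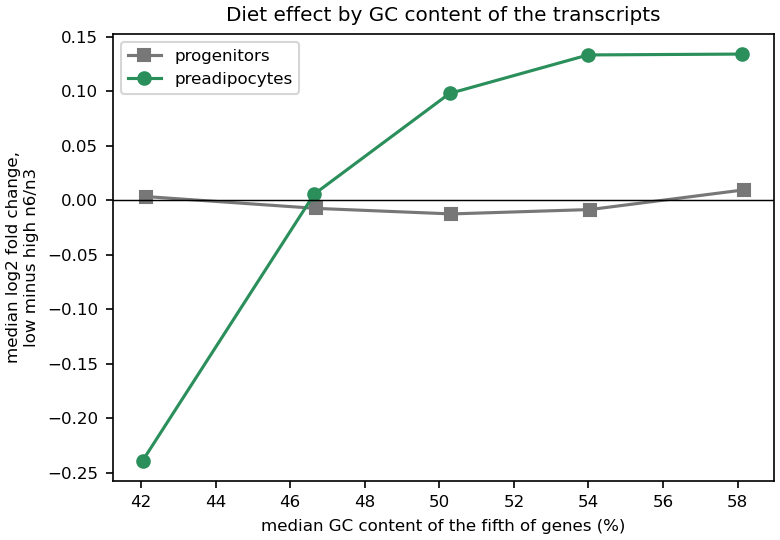
Median log2 fold change, low minus high milk ratio (y axis), in 5 equal bins of the tested genes ordered by GC content, placed at the median GC content of each bin in percent (x axis), for progenitors (grey squares) and preadipocytes (green circles). In preadipocytes the median goes from −0.24 in the lowest bin to 0.13 in the highest, and in progenitors all bins lie between −0.01 and 0.01.

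In progenitors, no gene passed the threshold between milks in limma. Mitochondrially encoded genes had higher values on low-ratio milk in 12 of 13 members, with a median log2 fold change of 0.39, and all 15 markers of interstitial progenitors had lower values, with a median of −0.14. The single genes with the smallest p values included Tep1, a telomerase-associated protein gene, at 505 ± 91.2 (SD, n = 4) on high-ratio and 1259 ± 355 normalized counts (SD, n = 4) on low-ratio milk, and the dynein gene Dnah2, at 213 ± 46.6 and 43.0 ± 23.2 (SD, n = 4 each). Of 15973 genes tested with limma, 0 passed an adjusted p of 0.05, and the smallest adjusted p was 0.397. At an unadjusted p under 0.05 there were 1099 genes, 602 higher and 497 lower, and 4.04% of genes had groups that did not overlap, where chance gives 2.86%. Without 1 library, 2 genes (high 1015), 2 (high 1018), 3 (high 1019) and 2 (low 114) passed, and 0 without any of the others. The authors' deposited table listed 101 genes at an adjusted p under 0.05, 61 higher and 40 lower, of which 98 were tested here.

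The genes named by the rule as having the smallest p in progenitors included, among higher values, Tep1 (log2 fold change 1.30 ± 0.20 SE, adjusted p = 0.397), Harbi1 (1.48), the mitochondrial arginine tRNA gene mt-Tr (1.91) and Crybg3 (0.72). Among lower values they were Phactr1, an actin regulator (−1.36 ± 0.19 SE, adjusted p = 0.397), Rnf121 (−0.93), Dnah2 (−2.42 ± 0.38 SE, adjusted p = 0.397), Kazn (−0.47) and Rgl1 (−0.66). In the authors' deposited table Tep1 had a log2 fold change of 1.32 and an adjusted p of 1.13e-05. Tep1 (ENSMUSG00000006281) lies on chromosome 14 from 50824059 to 50870560 on the minus strand and Phactr1 (ENSMUSG00000054728) on chromosome 13 from 42680623 to 43138526 on the plus strand. Of the genes always named, the nuclear receptor gene Nr2f2 had the smallest p, with 637 ± 74.7 against 983 ± 171 normalized counts (SD, n = 4 each; 0.62 ± 0.16 SE, adjusted p = 0.566). Cpt1a had 0.04 ± 0.10 (SE, adjusted p = 0.947), Ppargc1a 1.57 ± 1.03 (SE, adjusted p = 0.762), Pparg −0.03 ± 0.38 (SE, adjusted p = 0.989) and Pdgfra −0.02 ± 0.10 (SE, adjusted p = 0.972).

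Camera called 5 of the 27 lists in progenitors, and none of the calls held with an estimated correlation or with fry. Mitochondrially encoded genes were higher (camera adjusted p = 2.9e-09, and 0.68 with an estimated correlation). The list's median was 0.25 after the trend on GC content and transcript length was removed (camera adjusted p = 9.9e-05). Of its 13 genes, 7 passed the threshold when adjusted over the list alone. Among them were mt-Nd5 (0.39 ± 0.09 SE, adjusted p = 0.479 over all genes), mt-Atp8 (0.51) and mt-Nd6 (0.78). All genes with a symbol that starts with mt-, tRNA genes included, are a wider set than the list. They took 2.16%, 1.95%, 1.98% and 1.78% of normalized counts in the high-ratio libraries 1015, 1017, 1018 and 1019. In the low-ratio libraries 108, 114, 119 and 133 they took 2.38%, 2.67%, 2.72% and 2.16%. The interstitial progenitor markers were lower (camera adjusted p = 0.00044; adjusted p = 0.87 with an estimated correlation), with Anxa3 at −0.41, Wnt2 at −0.26 and Pi16 at −0.20. Extracellular matrix genes were lower (median −0.09 over 29 genes, camera adjusted p = 0.011; adjusted p = 0.86 with an estimated correlation), with Col3a1 at −0.22 and Col1a1 at −0.20. Glycolysis (median 0.13 over 17 genes, camera adjusted p = 0.015; adjusted p = 0.68 with an estimated correlation) and cholesterol synthesis (median 0.22 over 25 genes, camera adjusted p = 0.024; adjusted p = 0.94 with an estimated correlation) were higher, with Slc2a1 at 0.57, Pgk1 at 0.23 and Mvd at 0.41. In these 4 lists 0 genes passed when adjusted over the list alone.

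Mitochondrial fatty acid oxidation genes were not called in progenitors (median −0.07 over 22 genes, 0 past the threshold in either count, camera adjusted p = 0.51), with Etfa at −0.41. Ucp2, an uncoupling protein gene, had 0.77 ± 0.24 (SE, adjusted p = 0.631). Nr2f2 (higher) and Nr2f1 (−0.69 ± 0.19 SE, adjusted p = 0.591) passed in opposite directions when adjusted over the list of 13 stromal lineage and nuclear receptor genes alone, and Egr3 (0.88 ± 0.17 SE, adjusted p = 0.479) passed when adjusted over the list of 31 immediate early genes alone. Neither list was called (camera adjusted p = 0.98 and 0.8). Markers of endothelial cells were called higher on low-ratio milk (median 0.43 over 12 genes, 0 past the threshold and 1 when adjusted over the list alone, camera adjusted p = 0.0016; adjusted p = 0.45 with an estimated correlation), with Cdh5 at 1120 ± 273 and 2145 ± 905 normalized counts (SD, n = 4 each) and Pecam1 at 0.56. So were sex-linked genes (median 0.88 over 5 genes, camera adjusted p = 0.042; adjusted p = 0.45 with an estimated correlation), with Ddx3y at 0.88 and Xist at −0.70. Without progenitor high 1017 the calls of glycolysis (adjusted p = 0.0672) and cholesterol synthesis (0.0672) ended, as did that of cholesterol synthesis without high 1018 (0.591), low 114 (0.115) or low 133 (0.216), of glycolysis without low 119 (0.196) and of the extracellular matrix without low 108 (0.105) or low 114 (0.0784) or with quantile normalization (0.496).

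The milk effect differed between the populations in 350 of 15354 genes tested for the interaction, 96 with a higher and 254 with a lower effect in preadipocytes than in progenitors. At an unadjusted p under 0.05 there were 2704 genes, 1381 with a higher and 1323 with a lower effect. This fit treats libraries that share a number as independent. Without progenitor high 1018, which has no preadipocyte library, 177 genes passed. With a replicate block on the number, for which that library was left out too, 43 genes passed in limma. With the trend on GC content and transcript length removed as well, 0 passed (2063 at an unadjusted p under 0.05). The values that follow are from the fit of all libraries without the block. Mitochondrially encoded genes had a median difference of −1.37, with 10 of 13 past the threshold. The gene mt-Cytb had a milk effect of 0.16 in progenitors and −1.22 in preadipocytes, a difference of −1.37 ± 0.15 (SE, adjusted p = 0.0018). Fads2 had −0.29 in progenitors and 0.58 in preadipocytes (difference 0.86 ± 0.15 SE, adjusted p = 0.0144). Dnah2 had −2.42 in progenitors and 2.44 in preadipocytes, the largest difference among the genes named (4.86 ± 0.69 SE, adjusted p = 0.00498).

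After Dnah2, the largest positive differences were those of Gpd2 (4.17 ± 0.97 SE, adjusted p = 0.037; −1.17 in progenitors and 3.0 in preadipocytes), Donson (3.16 ± 0.39 SE, adjusted p = 0.00242), Ctnnd2 (1.92), Foxj3 (1.72), Zc3h12b (1.69), Tmem241 (1.66), Fam210a (1.60), Phlpp1 (1.58) and Crim1 (1.47). The largest negative differences included those of Vmn1r72 (−2.82), Arhgap15 (−2.47), mt-Nd6 (−2.12 ± 0.27 SE, adjusted p = 0.00266), Snhg14 (−2.11), the mitochondrial serine tRNA gene mt-Ts1 (−2.01), mt-Atp8 (−1.95 ± 0.23 SE, adjusted p = 0.00225), the neuronal RNA gene Bc1 (−1.91), Zfp967 (−1.90) and Pin4 (−1.85). The mitochondrial genes among them share or overlap with neighbours as described for preadipocytes.

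Camera called 6 lists in the interaction. Mitochondrially encoded genes (camera adjusted p = 2.7e-21) were also called with an estimated correlation (adjusted p = 0.036 with an estimated correlation) and with fry (adjusted p = 0.00011), and 12 of 13 were lower when adjusted over the list alone. Their median was −0.62 with the trend on GC content and transcript length removed (camera adjusted p = 9.3e-08), and that of ribosomal proteins −0.52 (camera adjusted p = 1.8e-13). Ribosomal protein genes (median −0.42, 12 of 48 lower and 22 when adjusted over the list alone, camera adjusted p = 1.2e-10) and nuclear respiratory chain genes (median −0.12, 8 of 50 lower and 12 when adjusted over the list alone, camera adjusted p = 0.00064) had lower differences, with Rpl24 at −1.67, Ndufb3 at −1.29 and Uqcrb at −1.28. Fatty acid synthesis (median 0.25, 1 of 15 higher in both counts, camera adjusted p = 0.01), interstitial progenitor markers (median 0.24, 0 of 15 past the threshold and 4 higher when adjusted over the list alone, camera adjusted p = 0.0065) and the extracellular matrix (median 0.24, 3 of 29 higher and 2 lower, 9 and 2 when adjusted over the list alone, camera adjusted p = 0.0022) had higher differences. Each of these 5 lists had an adjusted p = 0.78 with an estimated correlation. The call of fatty acid synthesis ended without preadipocyte high 1015 (adjusted p = 0.056), with quantile normalization (0.0576) and with the trend on GC content and transcript length removed (0.0596). That of interstitial markers ended without progenitor low 119 (0.0568), and that of the matrix with the trend removed (0.0571). In the matrix list Col1a1 had a difference of 0.67 (adjusted p = 0.0217), against −0.59 for Postn (adjusted p = 0.0232) and −0.65 for Lum (adjusted p = 0.0219).

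Across the 15354 genes, the estimated effects of milk in the populations were nearly uncorrelated: Pearson's r was 0.0169, Spearman's rho 0.0400 and 50.8% of genes had the same sign. Noise in the estimates also brings these values down, so they do not show that the true effects are unrelated. Genes are not independent replicates, and no p is given. Removing the trend on GC content and transcript length left 160 genes past the threshold of the interaction, 45 with a higher and 115 with a lower effect, and 129 of them among the 350. Leaving out 1 library gave 218, 128, 177 and 184 genes (progenitor high 1015, 1017, 1018 and 1019) and 215 and 165 (progenitor low 108 and 114). It gave 70, 95 and 846 genes (preadipocyte high 1015, 1017 and 1019), 137 and 108 (preadipocyte low 119 and 133), and between 261 and 304 without any of the other 4 libraries.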

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

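Of the tests in this part, the one on sequencing depth was chosen only after the result was seen. The correction for GC content and transcript length and the rescaling of the list tests were added after seeing the data, with their bounds written before their results. The list tests of the difference between populations were also added after seeing the data.

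In preadipocytes 458 genes passed the threshold between milks, as many as in 1 of the 35 splits of the 7 libraries, the real one (the highest other gave 6). This argues against chance only as far as 35 splits can show, where 1 of 35 is the smallest share possible. The splits cannot tell milk from anything else that goes with the groups. The median fold of the called genes was 0.982 with the balance of Y-linked genes to Xist as a covariate, against 0.981 without. These genes were called in the same data for folds large against the spread within groups. That leaves little room for a shift with the covariate, so the fold says little on the mix of sexes as a cause. With the covariate 0 genes passed in limma (1945 at an unadjusted p under 0.05) as the median SE went from 0.18 to 0.24. Removing the trend on GC content and transcript length left 9 of the 458 genes past the threshold: their median fold went from 0.98 (quartiles 0.73 to 1.20) to 0.75 (0.54 to 0.96) with a median SE of 0.18 and 0.16, so the calls ended with smaller folds and no larger median SE, at a median adjusted p of 0.0378 before and 0.0676 after. After removal of the trend 3036 genes had an unadjusted p under 0.05, which 1 of 35 splits, the real one, reached (the highest other gave 2106). The trend as fitted was thus not the whole difference. What a smooth fit fails to remove would follow the real split too, so the count cannot exclude the trend as its source. At an adjusted p of 0.05 the splits differed little after the removal, with 9 genes in the real one and 6 in the highest other. A part played by library preparation or RNA quality and one played by milk cannot be told apart for the genes whose call ended. The trend on GC content parts all 3 high-ratio from all 4 low-ratio libraries, while the trends on transcript length overlap.

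Mitochondrially encoded genes were lower in preadipocytes on low-ratio milk, with a median log2 fold change of −1.01. Depth is argued against, since the high-ratio libraries included both the shallowest and the deepest. The deepest still had a share of 5.83%, above the highest low-ratio share of 3.03%. That share is over all genes with a symbol that starts with mt-, a wider set than the list. A factor per library shifts all genes alike, so median-ratio rescaling could not move the list's median relative to all genes and tests nothing here. That relative median was −1.05 without rescaling and −1.01 under the rescaling that left it nearest 0. The fall is thus one relative to other genes, not a shift of all genes. The trend on GC content and transcript length stays open as a candidate explanation of part of the fall, since the median was −0.32 after its removal. GC content and length were removed together, so their parts cannot be told apart. RNA quality, mitochondrial content of the sorted cells and milk itself also stay open and were not tested.

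The effect of milk differed between populations in 350 genes in the fit without the replicate block. Of 35 splits of the numbers 1 reached that count, the real one (the highest other gave 2). This argues against chance only as far as 35 splits can show. In progenitors the count was 0 in limma, with 1099 genes at an unadjusted p under 0.05 and 101 in the authors' table. All 35 splits reach a count of 0 whatever the data, so the splits say nothing on chance there (the highest other gave 3). Milk effects went with GC content in preadipocytes (Spearman's rho 0.265) and hardly in progenitors (0.00722), where single libraries had trends from −0.134 to 0.102 with either sign on both milks. The differences hold part of the trend of preadipocytes, and 160 genes passed with the trend on GC content and transcript length removed.

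Single libraries lay far from the others of their group in 14 of 232 groups tested, where chance gives about 1 in 20, or 11.6. The test was not applied to groups of 3 libraries, so preadipocytes on high-ratio milk were not tested. Progenitor high 1019 had 59.3 M reads (others 40.4 M to 42.6 M) and progenitor low 114 had 34.4 M (38.6 M to 39.3 M). Progenitor high 1019 also had normalized counts of 369 for Tep1 (others 538 to 565), 1298 for Phactr1 (2190 to 2256), 5917 for Xist (1703 to 1863) and 103 for Gm3851 (0 in the others). In progenitor low 114, Pias4 had 672 (46.3 to 96.7) and Supv3l1 469 (31.1 to 41.1). Progenitor low 108 had 1788 for Tep1 (1033 to 1120), progenitor low 133 had 447 for Ndufb3 (534 to 548) and progenitor high 1015 had 493 for Tmem241 (411 to 424). In preadipocytes, low 114 had 187055 for mt-Cytb (152012 to 157924), low 133 had 2543 for Fads2 (2187 to 2204) and low 108 had 899.5 for Foxj3 (1457 to 1522). Gm3851, Pias4 and Supv3l1 were named after their values were seen. Pias4 and Supv3l1 passed in progenitors without low 114, and Gm3851 without high 1019. Their flags in those same libraries thus follow from how they were chosen. The count of 14 includes them, so it cannot be set against chance.

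Milk effects differed between populations by the test of the difference itself (preadipocyte minus progenitor, log2) for the mitochondrial genes mt-Nd6 (−2.12), mt-Ts1 (−2.01), mt-Atp8 (−1.95), mt-Nd4l (−1.48), mt-Cytb (−1.37) and mt-Nd5 (−1.14). They differed for Uqcrb (−1.28), Ndufb3 (−1.29) and Ndufa1 (−0.87) of the respiratory chain and for Rpl24 (−1.67), Rps12 (−1.15), Rps24 (−1.12) and Rpl35 (−0.94) of the ribosome. Positive differences were those of Dnah2 (4.86), Gpd2 (4.17), Donson (3.16), Ctnnd2 (1.92), Foxj3 (1.72), Zc3h12b (1.69), Tmem241 (1.66), Fam210a (1.60), Phlpp1 (1.58), Crim1 (1.47), Kazn (1.38), Rgl1 (1.05), Fads2 (0.86), Ephx1 (0.84), Cep170 (0.73), Col1a1 (0.67) and Sparc (0.56). Other negative differences were those of Vmn1r72 (−2.82), Arhgap15 (−2.47), Snhg14 (−2.11), Bc1 (−1.91), Zfp967 (−1.90), Pin4 (−1.85), Tep1 (−1.76), Ogn (−1.24), Ccl7 (−1.21), Mgst1 (−1.13), Prdx1 (−0.91), H3f3a (−0.73), Lum (−0.65) and Postn (−0.59). Among lists, the median differences were −1.37 for mitochondrially encoded genes, −0.42 for ribosomal proteins, −0.12 for the respiratory chain, 0.25 for fatty acid synthesis, 0.24 for interstitial progenitor markers and 0.24 for the extracellular matrix. Cep170 was named after its values were seen.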

How the results depend on the processing

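The GC correction, the deposited scale, rescaling of the list tests, the list tests of the interaction and the sex covariate there were chosen after seeing the data. Here the GC correction, or the GC trend removed, means the trend on GC content and transcript length removed together. Rescaling, filters, pseudocounts and the deposited scale gave 430 to 677 genes in preadipocytes, 303 to 511 in the interaction and 0 in progenitors (limma; 1099 at an unadjusted p under 0.05, 101 in the authors' table). Preadipocytes gave 1225 genes with quality weights, 1350 at a threshold of 0.1, 9 with the GC trend removed and 0 with the sex covariate (1945 at an unadjusted p under 0.05, 1834 in the authors' table without it), where the median SE of the called genes went from 0.18 to 0.24 at an equal fold. Of the 9, Gcc2, Cep170, Gm10259, Gm3851 and Gm48499 were named after their values were seen, and Gm10259, Gm3851 and Gm48499 are processed pseudogenes. The interaction gave 288 with the sex covariate, 669 with weights, 798 at 0.1 and 160 with the GC trend removed. Leaving out 1 library gave 0 to 3 genes in progenitors, 2 to 1160 in preadipocytes (2, Gm10259 and Gm48499, without low 108) and 70 to 846 in the interaction. The progenitor genes so called, chosen after their values were seen, were Gm12918 and Gm2808 (without high 1015), 1700030K09Rik and Flt3l (high 1018), Phactr1, Gm12184 and Gm3851 (high 1019) and Pias4 and Supv3l1 (low 114). Beyond the SE and folds given for the sex covariate and the GC trend, the cause of these changes was not tested.

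The labels do not say whether the numbers shared by the populations pair the libraries. Of 7 pairs, 0 correlated above 0.1 (−0.0594 to 0.0910, against −0.0912 to 0.130 in other pairs). These are correlations of deviations from the means of small groups, so low values cannot exclude that libraries of a number share animals. A replicate block on the number gave 43 genes in limma, 39 of them among the 350. It gave 0 with the GC trend removed as well (2063 at an unadjusted p under 0.05). The block needs both libraries of a number, so progenitor high 1018 was left out of it. Leaving out that library without the block gave 177 genes.

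Of the lists, 5 were called in progenitors (0 with an estimated correlation, 0 with fry, 3 to 7 with 1 library left out). In preadipocytes 9 were called (0 with an estimated correlation, 1 with fry, 5 with the GC trend removed, 4 to 10 with 1 library left out), and with that trend removed camera put immediate early genes lower instead of higher (median 0.00963, adjusted p = 0.876). In the interaction 6 were called (1 with an estimated correlation, 1 with fry, 5 with the GC trend removed, 5 to 7 with 1 library left out). Calls gained there were those of histone genes (adjusted p = 0.0259 with the GC trend removed, 0.0468 without preadipocyte low 133) and immediate early genes (0.0266 without progenitor high 1015, 0.0381 without preadipocyte low 108). The correlation of effects was −0.0175 without number 119 and 0.0422 without 114. No named gene past the threshold turned direction. Of all genes called, 457 of 458 in preadipocytes and 349 of 350 in the interaction kept their direction with the GC trend removed, and all did with the sex covariate. Estimated depth of 13.8 M reads in preadipocyte high 1015 limits genes with few reads. The tests on counts and the comparison of progenitors with preadipocytes were not run.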

Other observations

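The lists in this part were fixed before the data were examined, and of the tests in this part, quantile normalization of the lists and the list tests of the interaction were added after seeing the data. Calls in this part used camera at the preset correlation. With an estimated correlation and all libraries, 0 gene lists were called in either population. In preadipocytes, circadian clock genes had a median log2 fold change of 0.30 over 17 genes (camera adjusted p = 0.098) and genes of the unfolded protein response one of 0.14 over 20 genes (0.082), without being called. Interstitial progenitor markers had a median of 0.17 (adjusted p = 0.22), brown and beige adipocyte genes −0.31 (0.71), interferon response genes −0.04 (0.41), adipocyte differentiation genes −0.04 (0.9), committed preadipocyte markers 0.10 (0.94), Areg stromal markers 0.12 (0.84) and stromal lineage genes 0.12 (0.56). The circadian clock was called without high 1017 (adjusted p = 0.0238) or low 108 (0.0261), and interstitial markers without low 119 (0.0219).

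In progenitors, committed preadipocyte markers had a median of 0.21 over 14 genes and a camera adjusted p of 0.075. The list was called with quantile normalization (0.031) and without high 1015 (0.0122), high 1019 (0.0243), low 108 (0.0289) or low 133 (0.0122). NF-kB inflammatory genes were called higher without high 1019 (0.0108) or low 114 (0.0393), immediate early genes higher without low 114 (0.0341) and ribosomal proteins lower without low 119 (0.008). The other 21 lists had adjusted p values from 0.22 to 0.99. Of the marker lists not described with the comparisons, macrophage genes had a median of 0.24 in progenitors (adjusted p = 0.054), and erythroid genes one of −0.62 (0.0967). The other 7 marker lists measured in progenitors had adjusted p values from 0.20 to 0.54, the 9 not called in preadipocytes from 0.45 to 0.87 and the 10 of the interaction from 0.35 to 0.95. The median, the mean and the test differed in sign for 7 gene lists in progenitors, 6 in preadipocytes and 3 in the interaction, of which 0 were called by camera. Normalized counts of Xist were 1807, 1703, 1863 and 5917 in progenitor libraries 1015, 1017, 1018 and 1019 and 2403, 3065, 1136 and 575 in 108, 114, 119 and 133. In preadipocytes they were 4041, 3309 and 5425 in 1015, 1017 and 1019 and 3158, 1812, 757 and 432 in 108, 114, 119 and 133.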
